A study of Mus musculus with 8 samples.

How the data were processed

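Total RNA was sequenced from the dorsal lateral geniculate nucleus (dLGN), the thalamic relay for retinal input, of 8 mice labelled as aged 27 postnatal days. Of these, 4 are labelled wild type (Fn14 WT) and 4 knockout (Fn14 KO) for Fn14, the TWEAK receptor encoded by Tnfrsf12a. Groups below follow these labels. Per the labels' protocols, the nucleus was microdissected under a microscope from coronal brain sections of standard-housed littermates of both sexes, each mouse was an independent replicate, ribosomal RNA was depleted, and the fragmented RNA was sequenced on an Illumina NextSeq instrument. The sex and litter of each mouse are not given in the sources used here. Libraries are named by their label and replicate number, WT 1 to WT 4 and KO 1 to KO 4.

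The authors deposited 1 matrix of 8 libraries in TPM (transcript counts scaled by length and to a common sum per library), as its sheet name says, with the authors' mean per group beside it, and 23116 genes were analysed here. Those mean columns equalled the mean of the 4 libraries in every row within 0.003 TPM and were not used further. Per the submitters' processing notes, BWA and edgeR 3.14.0 were named, with the genome builds GRCm38 and mm10. Their settings, the gene annotation and the way reads of overlapping or near-identical genes were counted are not given in the sources used here. The TPM values analysed here summed to 969537 in WT 1 and 968958 in WT 2, and to between 996566 and 997426 in the other 6 libraries. Values have 2 decimals and no fixed step, so whole reads could not be recovered. Depth per library is therefore unknown, and no interval or floor from counting can be given. A gene at 0 is described as listed at 0. Of the 23116 genes, 2565 were listed at 0 in every library. Mitochondrially encoded genes were not analysed here. Gene positions came from GENCODE M21 on GRCm38. Of the 23116 genes, 20687 were placed by their symbol and 1899 by an older symbol.

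Values were analysed as log2(TPM + 1), with a pseudocount of 1 TPM, which understates the change of genes of low level. Genes with a mean of at least 1 TPM over the 8 libraries were tested, 15967 in all. KO was compared with WT by limma 3.58.1 in R 4.3.3 (a linear model per gene with moderated variances, mean-variance trend and robust estimation, two-sided), with no covariate and Benjamini-Hochberg adjustment at a threshold of 0.05. Every adjusted p below is from limma unless another test is named. Tnfrsf12a was also tested by an exact two-sided permutation test over the 70 assignments of the mice, for which the smallest possible p is 0.0286. Before the data were examined, 36 gene lists were fixed. Of these, 33 had at least 5 tested members and were tested with camera from limma, with the correlation between genes estimated per list and Benjamini-Hochberg adjustment over the 33 lists. A list of sex-linked genes and a list of genes neighbouring Tnfrsf12a were described and not tested, and 1 list had no member to test. Members not analysed here numbered 14 of 33 for myelin, 7 of 37 for thalamic relay neurons, 6 of 34 for astrocytes, 6 of 51 for axon guidance, 5 of 29 for glucocorticoid and circadian response, and at most 3 in each other tested list. A targeted allele can carry flanking sequence of another strain, so genes within 10 Mb of Tnfrsf12a were compared with the rest by Fisher's exact test for an unadjusted p under 0.01. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

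The limma step was tested on simulated data. Values for 15967 genes were drawn from the real means and the spread within groups of all 8 libraries, with 100 genes changed by 4-fold and 100 by 16-fold. The fit recovered 74% of the 4-fold and 96% of the 16-fold changes, with 5 false calls. With the spread of the 6 libraries other than WT 1 and WT 2 it recovered 85% and 95%, with 9 false calls. All changed genes had a mean level above that of Tnfrsf12a, so these rates do not cover genes of low level. Each gene was drawn independently, with the same spread in both groups. The rates therefore do not cover a shift shared by many genes in part of a group.

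Genes to name were fixed by rule before the data were examined. The rule took Tnfrsf12a and its ligand gene Tnfsf12, the 10 genes of smallest p in each direction past the threshold and without overlap between groups (filled up by smallest unadjusted p, and then said not to have passed), up to 3 members of smallest p from each tested list, Xist, Ddx3y, and the measured neighbours of Tnfrsf12a. Genes named outside this rule are said to be so. Alternatives fixed in advance were other pseudocounts, other filters on low values, quantile normalization, trimmed-mean-of-M-values (TMM) factors, rescaling without the 20 most abundant genes, other variance models, array weights per library, a replicate block, Xist level as a covariate, leaving out each library, other set tests, and other windows around Tnfrsf12a. The fit without both WT 1 and WT 2, the fit with Mbp level as a covariate and the filter on genes above 0 in all 8 libraries were added after the data had been seen. Count-based tests planned for whole reads could not be used on TPM.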

Results

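The dLGN transcriptome was measured in 4 mice labelled Fn14 WT and 4 labelled Fn14 KO, all labelled as postnatal day 27, to ask which transcripts differ when the TWEAK receptor Fn14 is absent. Between 16983 and 18756 genes had a value above 0 per library, and between 14784 and 16055 reached 1 TPM. Depth per library is unknown. All means are over 4 libraries per group unless another number is given.

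Tnfrsf12a, the gene for Fn14, lies on chromosome 17 from 23675445 to 23677468 on the minus strand (GRCm38). It was listed in all 8 libraries. The WT libraries gave 4.78, 5.48, 3.67 and 0.82 TPM and the KO libraries 2.95, 1.12, 1.32 and 1.86 TPM. The means were 3.69 ± 2.05 TPM in WT and 1.81 ± 0.82 TPM in KO (SD, n = 4 each). The library labelled WT 4 lay below all 4 KO libraries, against its label. The KO minus WT difference was −0.63 (SE 0.43) on the log2(TPM + 1) scale, which did not pass in limma (adjusted p = 0.45) or in the exact permutation test (p = 0.229). The part of the gene removed in the KO allele is not given in the sources used here, so reads outside a deletion would remain in these values. Without the library labelled WT 4 the difference was −1.03 (adjusted p = 0.161), without both WT 1 and WT 2 it was −0.09, and with array weights it was −1.33 and passed (adjusted p = 0.00115). Array weights nearly left out WT 3 and the library labelled WT 4 (weights 0.13 and 0.138). With them 6569 genes were higher and 3807 lower of 15967, so passing there is not particular to Tnfrsf12a. The ligand gene Tnfsf12 was at 3.19 ± 1.24 TPM in WT and 3.82 ± 0.657 TPM in KO (SD, n = 4 each), a log2 difference of 0.24 (SE 0.27) that did not pass.

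WT 1 and WT 2 stood apart from the other 6 libraries, and this split within the WT group bears on every comparison below. All 4 KO libraries lay on the side of the 6. Every KO minus WT difference below therefore carries part of this split, in a fixed direction, besides the wider spread. Mbp, a main protein of myelin, was at 11153 and 13566 TPM in WT 1 and WT 2 and between 34.4 and 51.3 TPM in the other 6. The next genes were chosen after their values were seen. Dcx, which marks migrating and young neurons, was at 5.08 and 9.50 TPM in WT 1 and WT 2 and between 368 and 619 TPM in the other 6. Tubb2b, a tubulin abundant in growing neurons, was at 106 and 115 TPM against 3033 to 4029 TPM. Across 15967 genes, WT 1 correlated with WT 2 at r = 0.979, WT 1 and WT 2 correlated with the other 6 at 0.822 to 0.869, and the other 6 correlated among themselves at 0.937 to 0.982. Genes are not independent replicates in these values. The first principal component held 65.5% of the variance and placed WT 1 and WT 2 at 109 and 100, with the other 6 between −42.8 and −29.6.

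**Figure D1:**
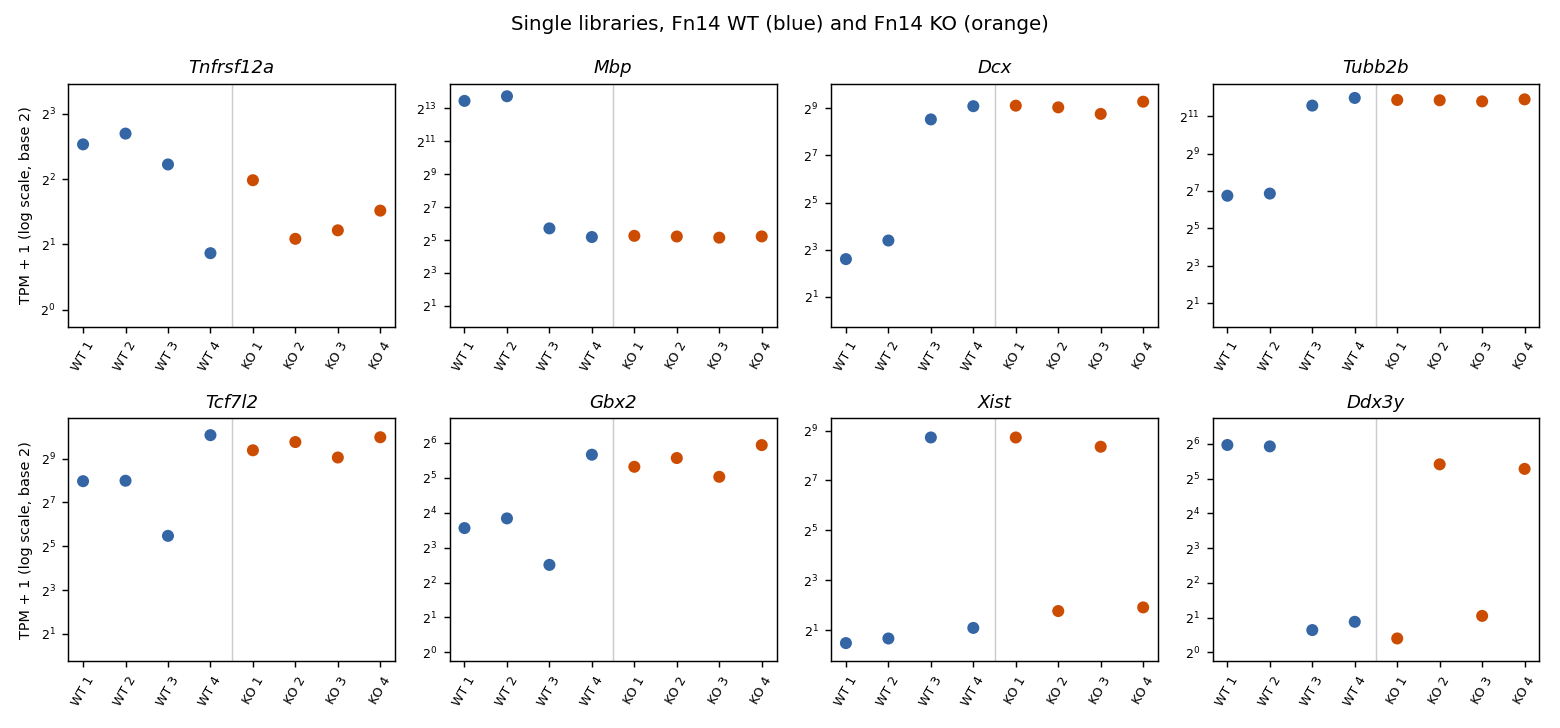
Level of 8 genes in each library (y axis: TPM + 1 on a log scale of base 2; x axis: library, Fn14 WT in blue and Fn14 KO in orange, 1 point per mouse). Mbp reached 11153 and 13566 TPM in WT 1 and WT 2 and 34.4 to 51.3 TPM in the other 6 libraries, and Tnfrsf12a was 0.82 TPM in the library labelled WT 4.

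Tissue markers also differed between libraries of the same group. Tcf7l2 and Gbx2, transcription factors of the thalamus chosen after their values were seen, were lowest in WT 3 at 43.4 and 4.68 TPM, while the other 7 libraries ran from 250 to 1074 TPM and from 10.8 to 60.4 TPM. Neurod6, a transcription factor of forebrain neurons, was at 140 TPM in KO 1 against 14.4 to 21.3 TPM in the other KO libraries and 7.42 TPM or less in WT. Ttr, the transthyretin gene of choroid plexus, was at 404 TPM in KO 1, 106 TPM in KO 2 and 94.8 TPM in WT 3, and at 45.0 TPM or less in the rest. Xist, transcribed from the inactive X chromosome, was at 422 TPM in WT 3, 422 TPM in KO 1 and 326 TPM in KO 3 and at 2.75 TPM or less in the other 5. The Y-linked gene Ddx3y was at 61.6, 59.9, 41.6 and 37.9 TPM in WT 1, WT 2, KO 2 and KO 4. The library labelled WT 4 had low values of both, with Xist at 1.12 TPM and Ddx3y at 0.84 TPM. The list of sex-linked genes, which follows the sexes of the mice, had 5 tested members, 2 above and 3 below 0, with a median log2 difference of −0.16.

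In the comparison of KO with WT, no gene passed the threshold. Limma called 0 genes higher and 0 lower of 15967, with a smallest adjusted p of 0.249. At an unadjusted p under 0.05, 851 genes were higher and 372 lower in KO, against 750 and 555 after quantile normalization and 697 and 512 with TMM factors. Where no gene differs, chance gives a share of about 0.05 of the 15967 genes. Genes vary together and the split within WT changes the spread, so counts at an unadjusted p do not measure a number of changed genes. The groups did not overlap for 534 genes, or 3.34%, where chance gives 2.86%, and 387 of these were higher and 147 lower in KO. Without both WT 1 and WT 2 the counts at an unadjusted p under 0.05 were 164 and 177, and 2 genes passed as lower, Mir135a-2 (log2 difference −3.12, adjusted p = 0.0447) and Mir199a-2 (−3.90, adjusted p = 0.0191). Mir135a-2 was chosen after its values were seen. It lies within Rmst on the same strand and Mir199a-2 overlaps Dnm3os, so read assignment is uncertain for both. The counts higher and lower at an unadjusted p under 0.05 were 199 and 105 without WT 1, 203 and 102 without WT 2, 3071 and 1201 without WT 3, and 2559 and 1764 without the library labelled WT 4. They were 354 and 191 without KO 1, 331 and 143 without KO 2, 636 and 297 without KO 3, and 289 and 145 without KO 4. With array weights, which gave WT 3 and the library labelled WT 4 weights of 0.13 and 0.138, 6569 genes were called higher and 3807 lower. The median log2 difference of all genes was 0.102 on the deposited scale, 0.019 with TMM factors and 0.002 after quantile normalization, and differences below are on the deposited scale.

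The 10 genes of smallest p in each direction had adjusted p from 0.249 to 0.429 and did not pass. Here and below, the SE of a gene is followed by its log2 difference without both WT 1 and WT 2. That fit sets the 4 KO libraries against WT 3 and the library labelled WT 4 alone. WT 3 had the lowest Tcf7l2 and Gbx2, and the library labelled WT 4 had Tnfrsf12a below all KO libraries. Values without both are therefore no clean estimate of a KO effect. Among those higher in KO, Epha7, an ephrin receptor on chromosome 4 (28813131 to 28967499), was at 54.8 ± 15.9 TPM in WT and 102 ± 9.76 TPM in KO (SD, n = 4 each), a log2 difference of 0.93 (SE 0.20, 0.82). Robo1, a receptor for Slit guidance cues, was at 64.4 ± 17.4 and 109 ± 10.9 TPM, a log2 difference of 0.78 (SE 0.20, 0.45). Inhba, which encodes a subunit of activin A, was at 1.90 ± 1.14 and 8.26 ± 3.92 TPM, a log2 difference of 1.67 (SE 0.40, 1.29). Gng8, a G protein gamma subunit, had a log2 difference of 1.65 (SE 0.37, 1.90) and Sh2d7 was at 1.17 ± 0.441 and 3.31 ± 0.745 TPM. The other 5 were small or noncoding RNAs. Snora62, Snord32a and Snhg9 were listed at 0 in all 4 WT libraries and at 2.88 to 6.78, 4.17 to 17.7 and 0.85 to 4.46 TPM in KO. Snord35b was listed at 0 in 3 WT libraries and at 5.55 TPM in WT 3, against 3.61 to 18.4 TPM in KO, and Rn4.5s had a log2 difference of 0.90 (SE 0.23, 0.59). By the annotation, Snora62 and Snord32a lie within the ribosomal protein genes Rpsa and Rpl13a, and Snhg9 overlaps Rps2 on the opposite strand, so how reads were divided between them is uncertain.

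Among the 10 genes lower in KO, Cryba1, a beta crystallin gene on chromosome 11 (77718615 to 77725283), was at 3.39 ± 0.79 TPM in WT and 0.767 ± 0.238 TPM in KO (SD, n = 4 each), a log2 difference of −1.31 (SE 0.24, −1.42). By the annotation, Cryba1 overlaps Nufip2 on the opposite strand, so its read assignment is uncertain. Akr1b10, an aldo-keto reductase gene, was at 20.5 ± 4.78 and 9.41 ± 2.78 TPM, a log2 difference of −1.05 (SE 0.25, −0.81). Mb, the myoglobin gene, had a log2 difference of −1.09 (SE 0.29, −0.95), Cml3 of −0.99 (SE 0.21, −0.81), Pold4, a DNA polymerase delta subunit, of −0.92 (SE 0.25, −0.67), and Hexa, a subunit of lysosomal hexosaminidase, of −0.71 (SE 0.19, −0.43). Ppp1r3c, which targets protein phosphatase to glycogen, had −0.54 (SE 0.15, −0.44), and the uncharacterised transcripts 4833412C05Rik and E030018B13Rik had −1.18 (SE 0.31, −0.88) and −0.92 (SE 0.25, −0.97). Mir199a-2 was listed at 0 in all 4 KO libraries and at 3.11, 1.66, 16.1 and 12.1 TPM in WT, and overlaps Dnm3 and Dnm3os.

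**Figure D2:**
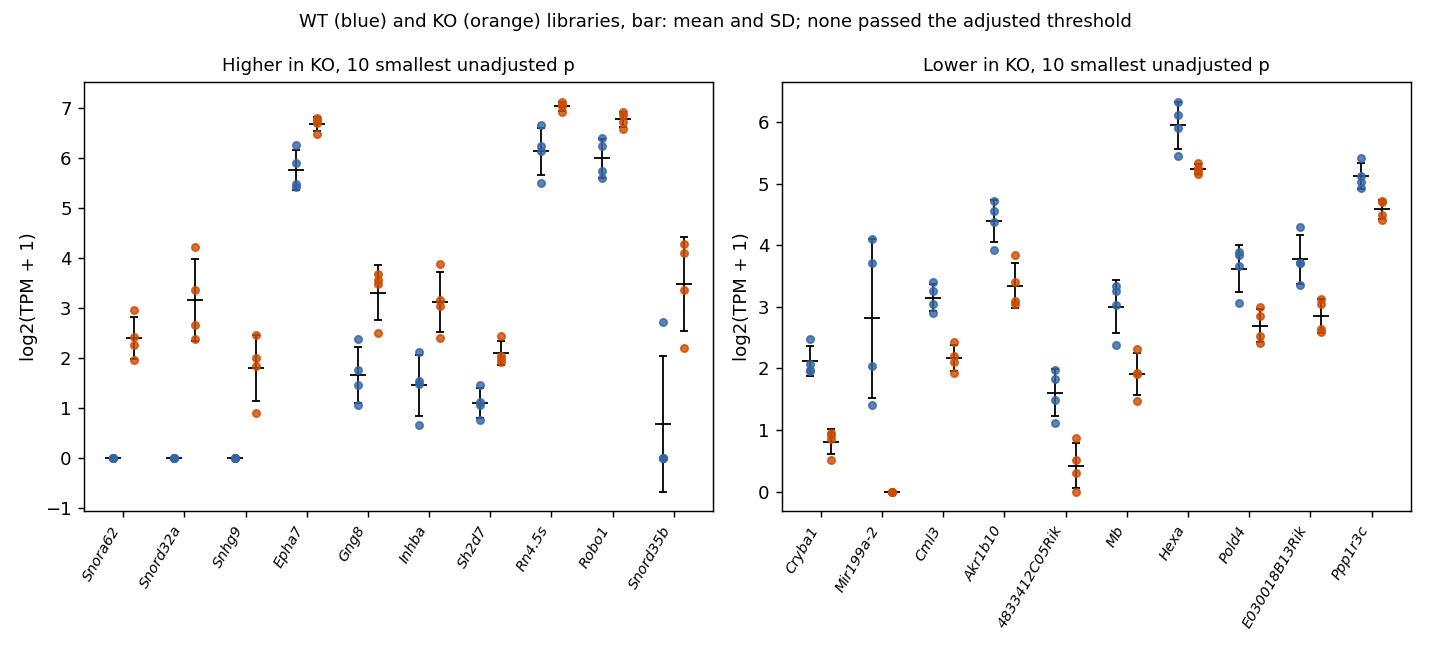
The 10 genes of smallest unadjusted p in each direction (y axis: log2(TPM + 1); points: libraries, Fn14 WT in blue and Fn14 KO in orange; black bars: mean and SD of 4 libraries). The groups do not overlap for 9 of the 10 genes higher and all 10 genes lower in KO, and none passed the adjusted threshold (smallest adjusted p 0.249). The genes were chosen for small p in this same comparison, which favours a lack of overlap, so it adds no support. Over all tested genes the share without overlap was 3.34%, where chance gives 2.86%.

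Of the 33 gene lists tested, none passed with an estimated correlation (adjusted p from 0.536 to 0.917). No member of any tested list passed, over all genes or adjusted over the list alone. With a preset correlation of 0.01, 16 lists passed, 11 lower and 5 higher in KO, and none of these calls held with an estimated correlation. For 25 of the 35 lists with values, the mean level of the list in WT 1 and in WT 2 lay outside the range of the other 6 libraries, above it for 14 and below it for 11. The medians below are of log2 differences over the tested members of a list, and each is followed by its value without both WT 1 and WT 2.

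Myelin and mature oligodendrocyte markers had the lowest median. Of 33 members fixed for the list, 14 were not analysed here, and all 19 tested members lay below 0 in KO, with a median of −2.27 and 0.07 without both WT 1 and WT 2. The adjusted p was 3.5e-09 with the preset correlation and 0.536 with an estimated correlation, which camera put at 0.97. Mbp had a log2 difference of −4.31 (SE 2.00, −0.24), Apod of −1.60 (SE 0.76, −0.12) and Ndrg1 of −0.98 (SE 0.47, −0.12). Oligodendrocyte precursor and immature oligodendrocyte markers split into 9 members above and 14 below 0, with a median of −0.39 and 0.07 without both, and included the sialidase gene Neu4 at −2.25 (SE 1.09, −0.07) and Sox6 at 0.45 (SE 0.19, 0.51). Astrocyte markers had 22 of 28 members below 0, with a median of −0.92 and −0.19 without both, and an adjusted p of 4.67e-07 preset and 0.536 with an estimated correlation. Agt, the angiotensinogen gene, stood at −2.56 (SE 0.94, −1.21) and the growth factor receptor gene Fgfr3 at −1.25 (SE 0.45, −0.57). Microglia markers had 27 of 29 members below 0, with a median of −0.51 and −0.12 without both, and an adjusted p of 3.5e-09 preset and 0.536 with an estimated correlation. Laptm5, a lysosomal membrane protein gene, stood at −0.62 (SE 0.20, −0.44) and Fcrls at −0.48 (SE 0.20, −0.27). Complement, MHC class I and synapse-pruning genes had 20 of 32 members below 0, with a median of −0.45 and −0.02 without both, among them C1qb of the C1q complex at −0.65 (SE 0.28, −0.22) and the TGF-beta receptor gene Tgfbr1 at 0.75 (SE 0.32, 0.16). Their adjusted p was 0.003 preset and 0.536 with an estimated correlation.

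Neuronal lists pointed both ways. Axon guidance genes had 36 of 45 members above 0, with a median of 0.67 and 0.17 without both WT 1 and WT 2, and an adjusted p of 0.002 preset and 0.536 with an estimated correlation. Besides Epha7 and Robo1, Sema3e, a class 3 semaphorin, was at 7.13 ± 1.40 TPM in WT and 11.8 ± 0.869 TPM in KO (SD, n = 4 each), a log2 difference of 0.67 (SE 0.18, 0.85). Markers of dLGN and thalamic relay neurons had 11 members above and 19 below 0, with a median of −0.26 and 0.45 without both. The mean log2 level of this list was 6.71 and 6.66 in WT 1 and WT 2, 4.53 in WT 3, 6.11 in the library labelled WT 4 and 5.09 to 6.41 in KO, so the value without both rests on WT 3. Their members of smallest p were higher in KO, with Calb2, the calretinin gene, at 1.85 (SE 0.51, 1.03), and the LIM homeobox genes Lhx2 at 2.58 (SE 0.70, 1.48) and Lhx9 at 2.47 (SE 0.78, 1.69). Habenula, hypothalamic and other diencephalic markers had 21 of 25 members above 0, with a median of 1.01 and 0.06 without both, including the nicotinic receptor subunit genes Chrna3 at 1.31 (SE 0.40, 0.67) and Chrnb4 at 1.01 (SE 0.29, 0.82). Their adjusted p was 0.008 preset and 0.654 with an estimated correlation. Ventral LGN and reticular GABAergic neuron markers had 20 of 27 above 0, with a median of 0.54 and −0.06 without both. In that list Otx2 stood at 0.87 (SE 0.31, 0.92) and Meis2 at 1.55 (SE 0.59, 0.63). Hippocampal neuron markers had 17 of 23 above 0, with a median of 0.47 and 0.25 without both. Among them Neurod6 stood at 3.32 (SE 0.95, 1.89) and Neurod2 at 2.72 (SE 0.78, 1.82), and KO 1 was the highest library for both.

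Synaptic and channel genes lay mostly below 0 in KO. Counts below 0 were 27 of 44 for glutamate receptors and postsynaptic scaffold, with a median of −0.20 and −0.02 without both WT 1 and WT 2, and 27 of 38 for presynaptic vesicle and release machinery, with −0.33 and 0.06. They were 18 of 24 for GABA synthesis, transport and receptors, with −0.51 and −0.10, and 28 of 41 for voltage-gated ion channels, with −0.19 and −0.01. Camk2a, a kinase of the postsynaptic density, stood at −1.53 (SE 0.72, −0.13), the sodium channel gene Scn1a at −1.65 (SE 0.71, −0.24) and Abat, which breaks down GABA, at −0.92 (SE 0.40, −0.32). Of the same list as Camk2a, Dlg1 stood at −0.57 (SE 0.26, −0.15), and Grm5 went the other way at 0.66 (SE 0.31, 0.14). In the presynaptic list the members of smallest p lay above 0, with Cplx2, a complexin, at 1.06 (SE 0.38, 0.38) and Syt4, a synaptotagmin, at 0.86 (SE 0.30, 0.30). The preset adjusted p of these 4 lists were 0.031, 0.009, 8.75e-04 and 0.004, and with an estimated correlation they were 0.536, 0.654, 0.536 and 0.536.

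Genes tied to activity and to TWEAK signalling showed no common direction. Immediate early genes had 13 members above and 20 below 0, with a median of −0.31 and 0.20 without both WT 1 and WT 2. Nr4a2 stood at 2.67 (SE 0.72, 1.51), Klf10 at 1.25 (SE 0.43, 0.43) and Gadd45b at −0.86 (SE 0.25, −0.66). Activity-regulated secreted and late-response genes had 12 above and 14 below 0, with a median of −0.13 and a mean of 0.07, opposite in sign, a camera direction of lower, and a median of 0.13 without both. Bdnf, the neurotrophin gene, was at 6.03 ± 2.48 TPM in WT and 12.1 ± 1.33 TPM in KO (SD, n = 4 each), a log2 difference of 0.96 (SE 0.28, 0.51). In the same list the neuropeptide gene Cartpt stood at 1.45 (SE 0.53, 0.69). TWEAK, TNF receptor family and TRAF genes had 16 above and 10 below 0, with a median of 0.08 that turned to −0.09 after quantile normalization, and 0.03 without both. Among them Ngfr, the p75 receptor, stood at 1.57 (SE 0.64, 0.32), Tnfsf9 at 1.18 (SE 0.48, 0.31) and Tnfsf13 at 0.88 (SE 0.39, 0.65). NF-kB pathway and target genes had 11 above and 14 below 0, with a median of −0.07 and −0.01 without both, including Nfkbia, the inhibitor of NF-kB, at −0.46 (SE 0.21, −0.13) and Mmp9 at 1.39 (SE 0.66, 0.33). Interferon-stimulated genes had 13 above and 15 below, with a median of −0.02 and −0.06 without both, with Ifit3 at −0.89 (SE 0.47, −0.06).

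Cell cycle genes had 30 of 32 members above 0, with a median of 0.90 and 0.20 without both WT 1 and WT 2, and an adjusted p of 5.58e-06 preset and 0.654 with an estimated correlation. Cdk1, the mitotic kinase gene, stood at 1.21 (SE 0.42, 0.56), Cdc20 at 1.32 (SE 0.52, 0.58) and Mcm7, a subunit of the replicative helicase, at 0.93 (SE 0.35, 0.34). Cytosolic ribosomal protein genes had 77 of 78 above 0, with a median of 0.47 and −0.08 without both, and an adjusted p of 8.58e-07 preset and 0.682 with an estimated correlation. Rpl22 stood at 0.80 (SE 0.33, 0.20) and Rps4x at 0.67 (SE 0.29, 0.21). Nuclear-encoded oxidative phosphorylation genes had 68 of 73 below 0, with a median of −0.26 and −0.05 without both, and an adjusted p of 5.85e-12 preset and 0.536 with an estimated correlation. Ndufa4 stood at −0.41 (SE 0.16, −0.25), Uqcrq at −0.30 (SE 0.12, −0.22) and Cox7b at −0.56 (SE 0.23, −0.22). Heat shock and unfolded protein response genes had 27 of 38 below 0, with a median of −0.26 and −0.03 without both, and the heat shock factor gene Hsf1 at −0.44 (SE 0.12, −0.34). Their adjusted p was 4.89e-05 preset and 0.547 with an estimated correlation. Glucocorticoid and circadian response genes had 19 of 23 below 0, with a median of −0.46 and 0.02 without both, the clock gene Per2 at −0.69 (SE 0.24, −0.31) and the metallothionein gene Mt2 at −1.33 (SE 0.48, −0.60). Their adjusted p was 9.34e-06 preset and 0.536 with an estimated correlation. Apoptosis genes had 17 of 26 above 0, with a median of 0.21 and 0.03 without both, with Mcl1 at 0.41 (SE 0.15, 0.21) and Endog at −0.90 (SE 0.28, −0.88). Cholesterol synthesis genes had 15 above and 14 below, with a median of 0.006 that lay below 0 under all 3 rescalings a mean of 0.001, a camera direction of lower, a median of −0.01 without both, and Fasn at 0.56 (SE 0.24, 0.17).

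Actin regulators had 33 of 48 members above 0, with a median of 0.23 and 0.06 without both WT 1 and WT 2, with Wasf1, a regulator of actin branching, at 0.42 (SE 0.17, 0.23). Extracellular matrix and perineuronal net genes had 25 of 41 above 0, with a median of 0.39 and 0.06 without both. In that list Col4a1, a basement membrane collagen gene, stood at 1.14 (SE 0.39, 0.41), and Bcan, the brevican gene, at −1.15 (SE 0.40, −0.57). Vascular and border tissue lists varied between libraries. Endothelial markers had 15 above and 14 below 0, with a median of 0.03 that turned to −0.08 after quantile normalization, a mean of −0.04 and a camera direction of lower. Their median was 0.02 without both. Mural and smooth muscle markers had 10 above and 8 below, with a median of 0.05 and 0.05 without both, which quantile normalization moved to −0.03. Meningeal and perivascular fibroblast markers had 20 of 23 above 0, with a median of 0.52 and 0.14 without both, and an adjusted p of 0.011 preset and 0.682 with an estimated correlation. Choroid plexus and ependymal markers had 18 of 23 above 0, with a median of 0.55 and 0.04 without both. Blood cell markers had 5 of 5 above 0, with a median of 0.69 and 0.36 without both, and were highest in KO 1, where the alpha globin gene Hba-a2 was at 1947 TPM against 253 to 826 TPM in the other 7 libraries.

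**Figure D3:**
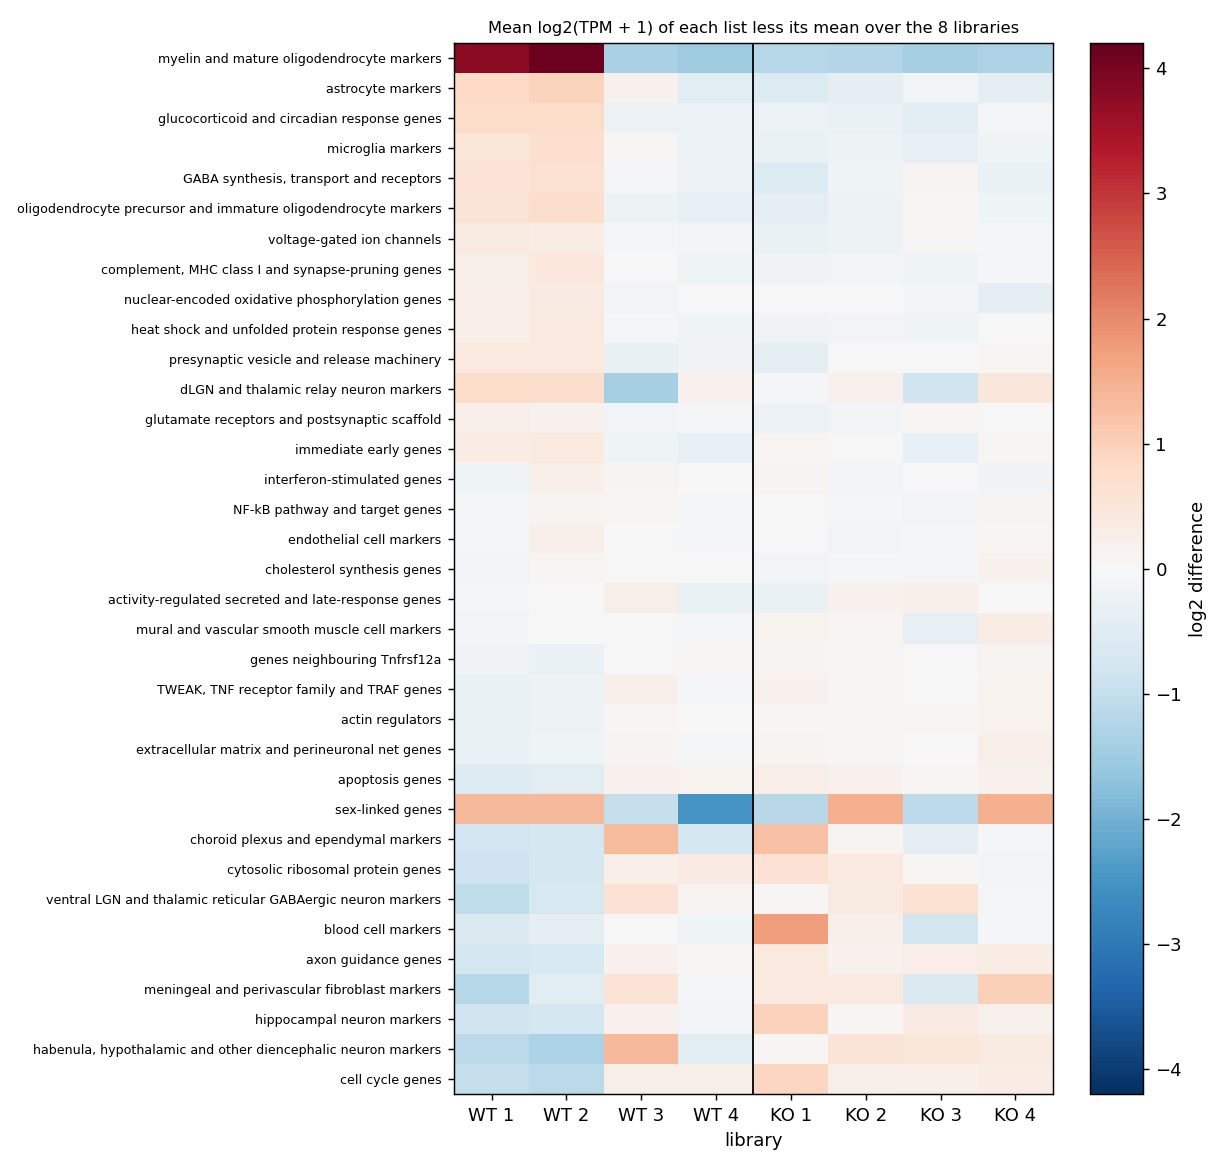
Mean log2(TPM + 1) of the tested members of 35 lists in each library, less the mean over the 8 libraries (rows: lists in order of KO minus WT; columns: libraries; colour: log2 difference). The KO minus WT value of the myelin list was −2.55, with its mean at 8.18 and 8.51 in WT 1 and WT 2 and 2.90 to 3.19 in the other 6 libraries.

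Genes flanking Tnfrsf12a did not stand out as a set. Within 10 Mb on chromosome 17, 2 of 272 genes were past an unadjusted p of 0.01 against 71 of 15387 elsewhere, an odds ratio of 1.60 (Fisher's exact test, two-sided, p = 0.363). With 2 such genes the test cannot exclude an effect of flanking sequence on single genes. Snhg9, named above among the genes higher in KO, is 1 of the 2, at 24719531 to 24719965. It was listed at 0 in all 4 WT libraries and at 0.85 to 4.46 TPM in KO. The odds ratio lay below 1, at 0.70, for an unadjusted p under 0.05 and was 0.69 without the library labelled WT 4, 2.98 without WT 1 and 3.15 without WT 2. Of the neighbouring genes, 12 including Tnfrsf12a were tested, 7 above and 5 below 0 with a median of 0.15 (0.005 without both WT 1 and WT 2), and none passed. Kremen2, a Dickkopf receptor gene, was at 4.26 ± 0.741 TPM in WT and 6.45 ± 0.803 TPM in KO (SD, n = 4 each), a log2 difference of 0.50 (SE 0.20, 0.46). Flywch1 stood at −0.54 (SE 0.29, 0.01), Pkmyt1 at 1.09 (SE 0.54, 0.07), Mmp25 at 0.56 (SE 0.35, 0.07), Cldn6 at 0.52 (SE 0.46, 0.32), Thoc6 at 0.33 (SE 0.23, 0.00), Tceb2 at 0.20 (SE 0.28, −0.26) and Flywch2 at 0.11 (SE 0.21, −0.21). Paqr4, Hcfc1r1 and Srrm2 stood at −0.16 (SE 0.28, 0.31), −0.03 (SE 0.16, −0.12) and −0.01 (SE 0.14, −0.13). Cldn9, Prss22, Prss27 and Prss33 were below the filter, with no library above 2.90 TPM.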

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

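The tests of the X chromosome ratio and of the splits were set before their results were seen, and the tests of the genes that escape X inactivation and of the Tnfrsf12a range were chosen after. Of 352 sets of 4 libraries examined (genes named here and list means), 19 held a library far from the other 3 by Dixon's ratio, where chance gives about 1 in 20, or 17.6. Mir666, Eif2s3y, Kdm6a, Kdm5c, Eif2s3x and Ddx3x were chosen after their values were seen.

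KO 1 accounted for 8 of the 19. In KO 1, the forebrain neuron genes Neurod6 and Neurod2 were high, at 140 TPM against 14.4 to 21.3 in the other KO libraries and at 74.2 against 7.42 to 10. Blood genes were also high in KO 1, with Hba-a2 at 1947 TPM against 503 to 598 and Alas2 at 32.5 against 15.5 to 17.5. Has2 was at 9.96 TPM against 4.96 to 5.12 and Tnfsf9 at 5.20 against 3.76 to 3.98. Its mean log2 level was 4.59 for the cell cycle list against 3.92 to 4.03, and 6.31 for the presynaptic list against 6.70 to 6.77.

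In KO 3, Gng8 was at 4.62 TPM against 10.2 to 11.8, Mir666 at 21.4 TPM against 0 in the other 3, and the mean of the immediate early genes at 3.39 against 3.74 to 3.81. In KO 4, Endog was at 9.26 TPM against 18.5 to 20.9 and Meis2 at 15.2 against 41.7 to 45.8. In WT 3, Snord35b was at 5.55 TPM against 0, Kdm5c at 85.2 against 54.3 to 56.9, Xist at 422 against 0.39 to 1.12, and the mean of the choroid plexus and ependymal list at 3.83 against 1.71 to 1.78. In the library labelled WT 4, Lhx9 was at 159 TPM against 14.5 to 19.6. In WT 1, Prss22 was at 0.11 TPM against 0.

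The library labelled WT 4 had Xist at 1.12 TPM, where 3 libraries had 326 to 422 TPM, and Eif2s3y at 1.08 TPM, where the other 4 libraries with low Xist had 70.2 to 87.5 TPM. Were 2 X chromosomes active, the median log2 ratio of 549 X-linked genes to KO 2 and KO 4, less the autosomal median, would be at least 0.5. It was −0.024, which argues against that explanation. A single X chromosome without a Y may account for the pattern, since all 4 of the genes examined that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) lay below each Xist-positive library. A library built from an outside sample was not tested.

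Tnfrsf12a in the library labelled WT 4 was 0.82 TPM, below the KO range of 1.12 to 2.95 TPM. A KO library under a WT label could give this value, and the data do not decide it, since KO libraries list the transcript themselves and WT 3 at 3.67 TPM lies close to KO 1 at 2.95 TPM. A difference between mice of the same genotype stays open and was not tested.

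Limma called 0 genes past the threshold between KO and WT (851 higher and 372 lower at an unadjusted p under 0.05), and the highest count among the other splits of the libraries into 4 and 4 was 4. Any of the 35 splits reaches a count of 0, so 35 of 35 is fixed by that count and says nothing about chance. At an unadjusted p under 0.05, the 15 splits that keep WT 1 and WT 2 together gave 1063 to 2507 genes and the other 20 gave 40 to 225, which points to a structure of the samples. The split by label gave 1223. Among the 15, only WT 1 and WT 2 with KO 1 and KO 3 gave fewer, at 1063. The 851 and 372 genes are thus no more than most of these regroupings gave.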

How the results depend on the processing

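Alternatives were set before the data were examined, except the fits without both WT 1 and WT 2, with Mbp level as a covariate and on genes above 0 in all 8 libraries. The planned count-based tests on whole reads (edgeR quasi-likelihood and DESeq2) were not run, because TPM gives no reads, and the filter at a mean of 5 TPM leaves out Tnfrsf12a. Unknown depth limits what can be said of genes of low level. The counts of 0 genes higher and 0 lower were kept under all alternatives except these. Without trend and robust estimation 1 gene was higher (Snora62). With array weights 6569 were higher and 3807 lower, with weights of 0.13 for WT 3 and 0.138 for the library labelled WT 4. With Mbp as a covariate 1 was higher (Apol7e) and 2 lower (Mir135a-2 and Mir199a-2), and the same 2 were lower without both WT 1 and WT 2. Leaving out each library gave 0 higher, and 0 to 1 lower (Mir666 without KO 3). Counts at an unadjusted p under 0.05 then ran from 199 (without WT 1) to 3071 (without WT 3) higher and from 102 (without WT 2) to 1764 (without the library labelled WT 4) lower. Gene lists past the threshold stayed at 0 in every fit and with fry (smallest adjusted p = 0.44), and were 16 with the preset correlation of 0.01. Permutation of list means also gave 0 (smallest adjusted p = 0.471), but its smallest possible p of 0.0286 before adjustment over 33 lists leaves little room to pass, so it says nothing about stability. Without both WT 1 and WT 2, 11 of 33 lists turned direction, and 13 with the Mbp covariate. The log2 difference of Tnfrsf12a was −1.03 to −0.42 when a library was left out, −0.09 (SE 0.45) without both WT 1 and WT 2 and −0.04 (SE 0.41) with Mbp as a covariate, and passed only with array weights (−1.33, adjusted p = 0.00115). The odds ratio of genes near Tnfrsf12a turned below 1 without a filter (0.83), at a mean of 5 TPM (0), on genes above 0 in all libraries (0) and for p under 0.05 (0.70), and ran from 0.69 to 3.15 when a library was left out. The causes were not tested. The replicate numbers showed no pairing of the mice (correlations of deviations −0.10, 0.07, 0.06 and 0.03, against −0.24 to 0.21 for pairs of other numbers). The split of WT 1 and WT 2 could hide a pairing, so pairing is not excluded. The replicate block gave 0 genes higher and 0 lower, with 901 and 318 at an unadjusted p under 0.05.

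Apol7e, Mir135a-2, Mir666, Eif2s3y and Tubb2b were chosen after their values were seen. Of 136 named genes, 125 kept their direction under each alternative that gave them a value, which was 113 genes at a mean of 5 TPM, 122 above 0 in all libraries, 134 after rescaling, 135 with each covariate and 136 otherwise. Without both WT 1 and WT 2, log2 differences turned to 2.28 for Ddx3y, 2.51 for Eif2s3y, 0.0055 for Flywch1, −0.21 for Flywch2, 0.31 for Paqr4 and −0.26 for Tceb2. With Mbp as a covariate they were 2.42, 2.66, 0.0336, −0.22, 0.32 and −0.28 for the same genes, 0.0597 for Neu4, −0.0190 for Thoc6 and −0.0611 for Tubb2b. With Xist as a covariate they were 1.12 for Ddx3y, 1.59 for Eif2s3y and 0.0451 for Paqr4. Quantile normalization gave −0.00356 for Flywch2 and array weights gave 0.0759 for Srrm2. When 1 library was left out, the range ran from −1.22 to 0.559 for Ddx3y, −1.22 to 0.937 for Eif2s3y, −0.0651 to 0.217 for Flywch2, −0.107 to 0.0675 for Hcfc1r1, −0.378 to 0.0241 for Paqr4 and −0.0627 to 0.0516 for Srrm2. The causes were not tested.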

Other observations

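The test of the maturation gene pairs was set before its result was seen, and the tests of Fn14 loss, of scaling and of thalamic genes were chosen after. WT 1 and WT 2 differed from the other 6 libraries in the means of the myelin and synaptic lists, although all 8 mice are labelled as the same age. They also differed in Dcx and Tubb2b, genes of young neurons chosen after their values were seen. A candidate explanation is younger tissue in the 6 libraries than in WT 1 and WT 2. In 5 of 6 pairs of a gene that rises and a gene that falls as the brain matures, the ratio was lower in each of the 6. The pair Slc12a5 and Slc12a2 was the exception, at a log2 ratio of 0.84 and 0.50 in WT 1 and WT 2 and 0.84 to 2.78 in the 6. A single scaling factor per library is argued against, because the lowest log2 ratio of Mbp to Tubb2b in WT 1 and WT 2 exceeded the highest of the 6 by 12.56, where the 6 spanned 0.93. Loss of Fn14 cannot be told apart by its test. Mbp lay within 2-fold of the KO range in 2 of the 4 WT libraries. These were WT 3 and the library labelled WT 4, whose label is in doubt. WT 1 and WT 2 define the pattern, so only WT 3 could count. WT 3 had Mbp at 51.3 TPM, with Tnfrsf12a at 3.67 TPM against 1.12 to 2.95 TPM in KO. The pattern thus occurred in 1 library labelled WT with Tnfrsf12a above the KO range, which is too few to decide. Tissue without thalamus cannot be told apart for the 6 as a set, because 2 measures disagree. The mean of the thalamic relay list lay below WT 1 and WT 2 in all 6 libraries. Tcf7l2, Gbx2 and Lhx9, however, all lay above both in 5 of them, with Tcf7l2 at 529 to 1074 TPM against 250 and 253 TPM. Only in WT 3 did Tcf7l2 and Gbx2 lie below both, at 43.4 and 4.68 TPM.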
